A study of Mus musculus with 8 samples.

How the data were processed

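Gene expression was measured by RNA sequencing in 8 libraries of epithelial cells from mouse skin epidermis, made from cells isolated by fluorescence-activated cell sorting (FACS). Per the labels' protocols, cells were sorted into lysis buffer, polyA RNA was purified with the RNeasy Micro kit (Qiagen), its quality was read on a Bioanalyzer 2100 (Agilent), and indexed cDNA libraries were made with the Ovation Solo RNA-seq system (NuGen). The labels give 4 groups of 2 libraries: K14 control, K14 ablation, Lrig1 control and Lrig1 ablation. Control animals are labelled wild type and ablation animals carry a basal lineage ablation. Krt14, whose protein is K14, is the keratin of basal epidermal cells and Lrig1 marks stem cells of the upper hair follicle. Whether K14 and Lrig1 name a genetic driver, a sorted population or the ablated lineage is not given in the sources used here, so both only name populations below. The labels do not say whether a group's libraries came from separate animals, so p-values measure only the spread between these libraries. It may be technical, but Y-linked reads (given last) argue for separate animals in ablation pairs.

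Per the submitters' processing notes, the reads were processed with Trimmomatic, STAR, Picard and HTSeq (version 0.11.1) on genome build GRCm38, also called mm10; the role and settings of each tool, the strand setting and the annotation release are not given in the sources used here. The deposited values are a normalised signal per gene, in 1 table of 32574 genes by 8 libraries. In each library the values are whole multiples of a single step within a tolerance of 0.001, which is what read counts divided by a size factor give: 100% of values came out as whole reads in every library. The program that made the size factors is not given in the sources used here. Of the columns, 4 name the ablation libraries in other words than the labels do, and these were matched to the ablation groups because no other group was left; their replicate numbers come from the column names, with 1.1 read as replicate 1. Gene symbols came from the deposited table, in which 61 symbols occur more than once. Coordinates were looked up for 32427 of the gene identifiers in the GENCODE annotation of GRCm38, release M21.

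The recovered depth was 6458636 to 11654135 reads per library. A floor of 3 reads corresponds to a normalised read count between 2.12 and 4.23, depending on the library, and covers counting error only, because reads amplified without molecular identifiers are not independent molecules. Replicates were compared before use by a chi-square test of their reads. All 4 pairs differed by more than sampling noise, with a chi-square per gene of 1.64 in K14 control, 2.77 in Lrig1 control, 31.4 in K14 ablation and 44.6 in Lrig1 ablation, and each pair was counted as 2 libraries. The test takes reads as independent, so duplicates of 1 sample would exceed it, and it does not show separate samples.

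Tests were run on log2(normalised read count + 1) with limma 3.58.1 in R 4.3.3, with a variance trend, in 1 fit of the 4 group means over all 8 libraries (4 residual degrees of freedom and 4.13 prior degrees of freedom). Fold changes are therefore on the log2(value + 1) scale, which understates the change of low genes. Genes needed a value of at least 1e-06 of the library total in at least 2 libraries, which left 18140 tested genes; 268 genes of the table were at 0 in all libraries. P-values were adjusted by the Benjamini-Hochberg method over all tested genes and the threshold was an adjusted p of 0.05, with no limit on fold. The comparisons were ablation against control within K14 and within Lrig1, the mean of these effects, their difference, and Lrig1 against K14 within control and within ablation. The overlap of the K14 and Lrig1 ablation calls is given as counts without the Fisher's exact test first chosen for it, which needs independent lists, while 1 fit gives both the same estimate of each gene's spread.

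Gene lists were fixed before the data were examined, as were the comparisons, the tests and most alternatives. They are 24 epidermal themes (basal keratinocytes, epidermal differentiation, activated keratinocytes, upper hair follicle, hair follicle bulge and germ, sebaceous gland, cell cycle, basement membrane and matrix, matrix proteases and inhibitors, integrins and focal adhesion, actin cytoskeleton, cell-cell junctions, EGFR ligands and feedback, YAP/TAZ targets, AP-1 with immediate early and dissociation stress genes, cytokines and inflammation, interferon response, mesenchymal transition, p53 targets, unfolded protein and integrated stress, glycolysis and hypoxia, cholesterol synthesis, nuclear-encoded oxidative phosphorylation, and Wnt, Notch, Hedgehog and BMP signalling) and 8 other cell types (fibroblasts, endothelial and mural cells, myeloid and Langerhans cells, T cells, neutrophils, melanocytes, Merkel cells and erythroid cells). The 28 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided and adjusted over the lists; camera with an estimated correlation and fry were alternatives. Camera asks whether a list moved relative to the other genes, and fry whether its genes moved on balance one way.

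Genes named in the text were chosen by a rule. Krt14 and Lrig1 are always named. In each comparison, among genes past the threshold whose higher group had a mean log2 value at or above the median tested gene (6.81) and whose libraries did not overlap between the groups (in both populations for the averaged effect), the 10 largest rises and the 10 largest falls were taken, or 5 and 5 for the population comparisons and for the difference of effects. Groups of 2 libraries separate by chance in 33.3% of cases. Predicted genes were passed over, and where fewer than 10 passed, the smallest unadjusted p-values filled the places. For each list up to 4 members with the smallest p are named, and for each other cell type the 3 most abundant members. Some genes that the rule takes are not reported here, and they stay in the counts. A gene named outside this rule is stated to have been chosen after its values were seen.

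The alternatives were pseudocounts of 5 and 0.5, no filter and a filter 5 times stricter, median-ratio rescaling, quantile normalization, limma without the trend, array weights, only the compared groups in the fit, the replicate number as a block, each library left out in turn, an adjusted p of 0.1, an absolute log2 fold change of at least 1, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. A group left with 1 library is assumed to vary like the others. Y-linked expression as a covariate and leaving out both second ablation libraries were added after the data were seen. The tests were tried on simulated reads with 100 genes changed by a log2 of 1 and 100 by 2. K14 recovered 22% and 90% (8 false calls of 120). Lrig1 gave 26% and 89% (13 of 128) and the average 73% and 97% (9 of 179). Libraries shared 1 spread per gene, unlike real pairs. In simulated K14 data camera found 1 shifted list (adjusted p = 5.37e-58; 0.00426 with an estimated correlation) and called 0 others. This vouches for no real call: 0 held with the estimate.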

Results

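The series asks how clones of epidermal cells expand and how the tissue becomes fluid during skin repair, and for this it profiled basal epidermal cells with and without ablation of the basal lineage. RNA from sorted epithelial cells of mouse skin epidermis was sequenced in 8 libraries, 2 each of K14 control, K14 ablation, Lrig1 control and Lrig1 ablation. The recovered depth was 8268919 and 8575279 reads in K14 control, 11654135 and 7767292 in K14 ablation, 7621768 and 6458636 in Lrig1 control, and 8874869 and 9108072 in Lrig1 ablation. Mitochondrial genes took 2.34 to 2.91% of the normalised reads in the K14 libraries, 6.29 and 6.89% in Lrig1 control, and 3.14 and 4.14% in Lrig1 ablation.

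Krt14 (ENSMUSG00000045545, GRCm38 chromosome 11, 100203162 to 100207548, minus strand), the basal keratin, was abundant in every group. Its normalised read count was 60260 ± 1510 in K14 control, 77760 ± 2670 in K14 ablation, 43020 ± 1750 in Lrig1 control and 48970 ± 29600 in Lrig1 ablation (SD, n = 2 each). It did not pass the threshold in any of the 6 comparisons. Lrig1 (ENSMUSG00000030029, chromosome 6, 94604529 to 94700158, minus strand), a transmembrane brake on EGF receptor signalling, was 585 and 656 in the K14 control libraries and 4013 and 4194 in the Lrig1 control libraries, with a log2 difference of 2.73 ± 0.59 (SE; limma adjusted p = 0.0286). That call was lost without K14 control 1 (adjusted p = 0.183), K14 control 2 (0.159), Lrig1 control 1 (0.17) or Lrig1 control 2 (0.186). Lrig1 was 922 ± 798 in K14 ablation and 2655 ± 1300 in Lrig1 ablation, and neither ablation effect on it passed (limma adjusted p = 0.897 in K14 and 0.548 in Lrig1).

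**Figure D1:**
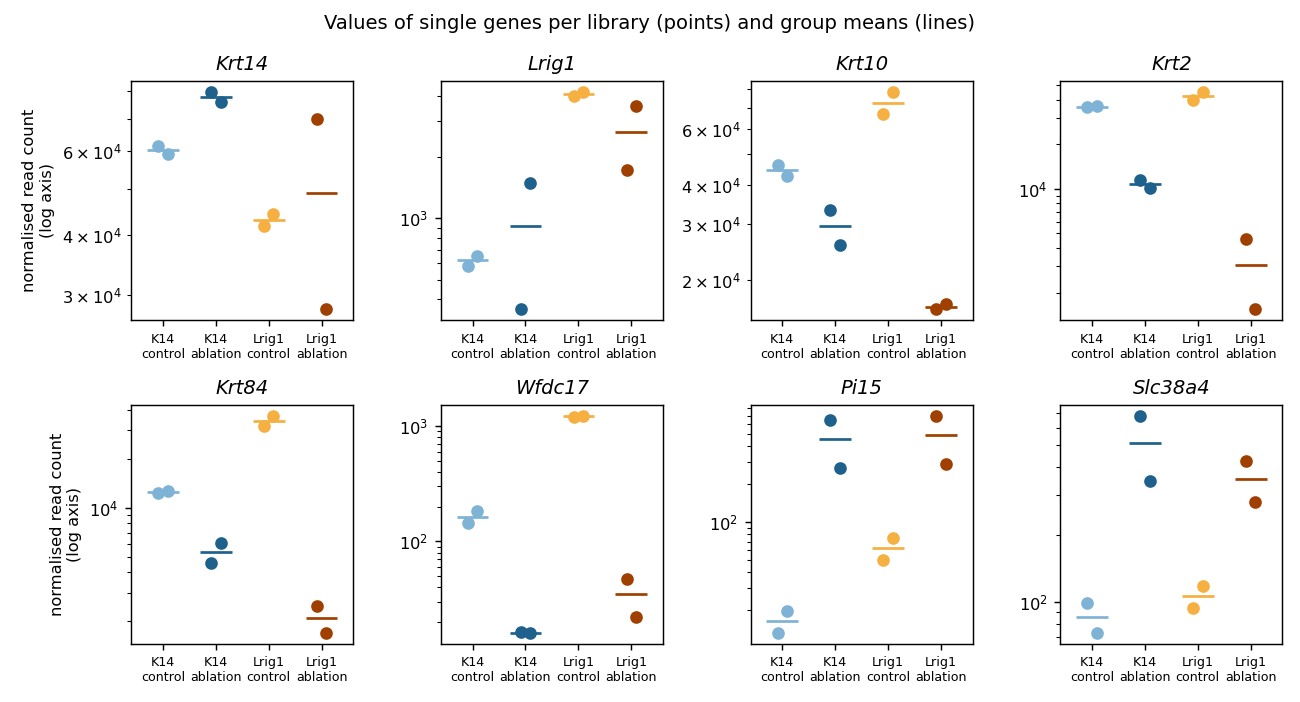
Normalised read count (log axis) of Krt14, Lrig1, Krt10, Krt2, Krt84, Wfdc17, Pi15 and Slc38a4 in the 4 groups; each point is a library and each line a group mean. Pi15 lies at 13.2 to 74.7 in the control libraries and at 270 to 701 in the ablation libraries, and Krt84 at 12350 to 36930 and 1693 to 6095.

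The comparison of K14 ablation with K14 control asks what ablation did in the cells labelled K14. Pi15 (ENSMUSG00000067780, chromosome 1, 17601901 to 17630939, plus strand), a secreted protein of the CRISP family, went from 16.5 ± 4.59 to 457 ± 264 normalised reads (SD, n = 2 each). Its log2 fold change was 4.61 ± 0.51 (SE; limma adjusted p = 0.0286). The adhesion receptor gene Flrt2 rose by 2.65 ± 0.26 on the log2 scale, the amino acid transporter gene Slc38a4 by 2.51 ± 0.35 and the membrane protein gene Myadm by 2.19 ± 0.17. Krt17, a keratin of stressed and follicular keratinocytes, rose by 1.70 ± 0.17, from 1992 ± 128 to 6498 ± 1100. The other named rises were Soga1, Vsnl1, Ltbp1, which encodes a binding protein of latent TGF-beta, and Megf6, by 1.31 to 2.24. Wfdc17 (ENSMUSG00000069792, chromosome 11, 83703991 to 83706268, plus strand), a small secreted protein of the whey acidic protein family, went from 163 ± 28.2 to 16.2 ± 0.136. Its log2 fold change was -3.25 ± 0.33 (limma adjusted p = 0.0159). Hhip, an inhibitor of Hedgehog ligands, fell by 2.49 ± 0.30, the cytochrome P450 gene Cyp3a13 by 2.18 ± 0.21 and the polarity gene Pard3b by 1.92 ± 0.23. The actin nucleator gene Cobl fell by 1.69 ± 0.15 and Errfi1, a feedback inhibitor of EGF receptor, by 1.53 ± 0.16. Grik4, Tprg, Dapl1 and Utp14b also fell, with log2 fold changes of -2.46 to -1.47.

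In all, 34 of 18140 genes passed in K14, 18 higher and 16 lower (limma; 2327 at an unadjusted p under 0.05, and 32 by edgeR). The count was 0 without either K14 control library or either Lrig1 control library (835, 997, 1678 and 1671 genes at an unadjusted p under 0.05 in limma). It was 16 without K14 ablation 1 (6 higher and 10 lower), 262 without K14 ablation 2 (47 and 215), 685 without Lrig1 ablation 1 (323 and 362) and 740 without Lrig1 ablation 2 (362 and 378). DESeq2 called 203, and limma fitted to the K14 libraries alone called 0, with 3565 at an unadjusted p under 0.05. Of the 24 named genes past the threshold, 0 still passed without any of the 4 control libraries, 6 did without K14 ablation 1, and 24 did without each of the other three ablation libraries.

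Of the gene lists, 13 moved in K14 ablation, 10 up and 3 down (camera). With an estimated correlation 0 of these calls held in any comparison, so each list below carries that p. In K14, 2 lists had an unadjusted p under 0.05 with it, and fry called 1. The cell cycle list moved up: 31 of 34 members had positive values, with a median log2 fold change of 0.54 (camera adjusted p = 1.93e-06, and adjusted p = 0.675 with an estimated correlation). Single members past the threshold numbered 0, and 0 adjusted over the list alone (limma; 8 at an unadjusted p under 0.05). Oxidative phosphorylation genes had positive values in 21 of 21 members, with a median of 0.34 (camera adjusted p = 0.000415, and adjusted p = 0.675 with an estimated correlation) and 0 past the threshold, alone or over all genes (2 at an unadjusted p under 0.05). Glycolysis and hypoxia genes had a median of 0.45 (camera adjusted p = 0.00489, and adjusted p = 0.675 with an estimated correlation), again with 0 of 23 past either way and 9 at an unadjusted p under 0.05. The glycolysis call was lost without K14 ablation 1 (camera adjusted p = 0.144).

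In the activated keratinocyte list (median 0.39, camera adjusted p = 0.00549, and adjusted p = 0.524 with an estimated correlation), 1 of 17 members rose, Krt17, and 4 rose and 1 fell adjusted over the list alone. The activated keratinocyte call was lost without K14 ablation 1 (camera adjusted p = 0.214). Krt6a was at 1.94 ± 0.33 and Krt6b at 2.55 ± 0.50. Krt17 is shared with the upper hair follicle list (median 0.24, camera adjusted p = 0.0215, and adjusted p = 0.675 with an estimated correlation), where it was the 1 riser of 15, and 5 rose and 1 fell over the list alone. That list's call ended without K14 ablation 2, with a median of -0.69 (adjusted p = 0.943), and without Lrig1 ablation 1 (0.156) or Lrig1 ablation 2 (0.168). Actin genes had a median of 0.13 (camera adjusted p = 0.0293, and adjusted p = 0.675 with an estimated correlation), and the call was lost without K14 ablation 1 (camera adjusted p = 0.193). Of 34 members 2 rose, the cross-linker gene Actn1 by 1.1 ± 0.14 and the calponin gene Cnn2 by 1.30 ± 0.17, with 3 up and 1 down over the list alone. In the mesenchymal transition list (median 0.62, camera adjusted p = 0.00489, and adjusted p = 0.525 with an estimated correlation) 0 of 13 passed, against 6 up and 1 down over the list alone and 7 at an unadjusted p under 0.05. The mesenchymal call was lost without K14 ablation 1 (camera adjusted p = 0.0943).

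The differentiation, AP-1 and YAP/TAZ lists moved down by camera. The differentiation list had a median of -0.49 (camera adjusted p = 0.00338, and adjusted p = 0.624 with an estimated correlation), with 0 of 25 past the threshold, 2 up and 7 down adjusted over the list alone and 11 at an unadjusted p under 0.05. The differentiation call was lost without K14 ablation 2 (camera adjusted p = 0.198). The AP-1 and immediate early list had a median of -0.40 (camera adjusted p = 1.3e-05, and adjusted p = 0.524 with an estimated correlation), with 0 of 23 past, 7 down over the list alone and 10 at an unadjusted p under 0.05. YAP/TAZ targets had a median of -0.32 (camera adjusted p = 0.0189, and adjusted p = 0.579 with an estimated correlation), with 0 of 21 past, 1 up and 2 down over the list alone and 6 at an unadjusted p under 0.05. The YAP/TAZ call was lost without K14 control 2 (camera adjusted p = 0.0742) or K14 ablation 1 (0.144).

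Lists of other cell types also moved up in K14 ablation. Myeloid and Langerhans genes had a median of 0.91 (camera adjusted p = 0.000641, and adjusted p = 0.524 with an estimated correlation), and the call was lost without K14 ablation 2 (camera adjusted p = 0.18). Endothelial and mural genes had a median of 0.98 (camera adjusted p = 0.00549, and adjusted p = 0.524 with an estimated correlation), and the call was lost without Lrig1 control 1 (camera adjusted p = 0.0719) or Lrig1 control 2 (0.0726). Fibroblast genes had a median of 0.74 (camera adjusted p = 0.00338, and adjusted p = 0.524 with an estimated correlation). The 1 member past the threshold in these lists was the matrix gene Fbln1, at 1.26 ± 0.16 (limma adjusted p = 0.0322), which was above the median tested gene in both K14 control libraries already. Over the lists alone 3 of 14 myeloid, 1 of 9 endothelial and 3 of 9 fibroblast members rose, and 4 members of each had an unadjusted p under 0.05. The leukocyte gene Ptprc was at 2.60 ± 0.54, Mfge8 at 2.37 ± 0.44, Pdgfra at 2.17 ± 0.69 and Kdr, the VEGF receptor gene, at 0 in both control libraries, at least 2.19-fold higher against a floor of 3 reads.

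The comparison of Lrig1 ablation with Lrig1 control asks the same question in the cells labelled Lrig1. Here epidermal differentiation genes fell: 21 of the 25 measured members passed, and 24 did adjusted over the list alone, with a median log2 fold change of -2.03 (camera adjusted p = 3.28e-25, and adjusted p = 0.129 with an estimated correlation). Elovl4 (ENSMUSG00000032262, chromosome 9, 83778692 to 83806277, minus strand), which makes the very long fatty acids of the skin barrier, went from 3217 ± 77.8 to 562 ± 118 normalised reads (SD, n = 2 each). Its log2 fold change was -2.53 ± 0.17 (SE; limma adjusted p = 0.00103). Calm4 fell by 2.03 ± 0.18, Sbsn by 1.97 ± 0.20 and the cornification protease gene Casp14 by 1.89 ± 0.19. Sele, the endothelial adhesion receptor E-selectin, was 203 ± 20.4 in control and 0 in both ablation libraries, at least 80.5-fold lower against a floor of 3 reads per library. Its relative Selp fell by 6.28 ± 0.68, and Vwf, the clotting factor carrier of endothelium, was at -5.35 ± 0.81.

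The hair keratin genes Krt87, Krt31 and Krt81 were at -6.07 ± 0.84, -5.74 ± 0.84 and -5.31 ± 0.76, the hair protein gene Krtap7-1 at -5.62 ± 0.77 and the envelope gene Hrnr at -6.05 ± 0.53. Hair keratin genes are near-identical copies of each other in part, so their reads are uncertain where the authors' counting could split them. Slc15a2 (ENSMUSG00000022899, chromosome 16, 36750177 to 36784962, minus strand), a peptide transporter, went from 293 ± 66.9 to 2.43 ± 2.19, a log2 fold change of -6.56 ± 0.42 (limma adjusted p = 0.00103). The rises were smaller. Pi15 rose by 2.86 ± 0.51, from 62.4 ± 17.4 to 495 ± 291 (limma adjusted p = 0.0247). So did the actin bundler gene Fscn1 by 2.31 ± 0.48, the nucleoporin gene Nup210 by 1.89 ± 0.30, the adhesion gene Kirrel by 1.77 ± 0.33, Slc38a4 by 1.70 ± 0.35 and the clock gene Arntl2 by 1.69 ± 0.26. The kinesin genes Kif21b and Kif18b, the centromeric histone gene Cenpa and the polarity gene Mpdz rose by 1.52 to 1.60.

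In Lrig1 737 genes passed, 139 higher and 598 lower (limma; 3643 at an unadjusted p under 0.05; 587 by edgeR). The count was 181 without either K14 control library, 5 without Lrig1 control 1, 6 without Lrig1 control 2, 2498 without Lrig1 ablation 1 (644 higher and 1854 lower) and 2097 without Lrig1 ablation 2 (852 and 1245). Limma fitted to the Lrig1 libraries alone called 170 (5 and 165), and with array weights 451 (44 and 407). Of 70 named genes past the threshold, 29 still passed without K14 control 1, 30 without K14 control 2, 2 without either Lrig1 control library (where 7 were not tested), and 67 without either Lrig1 ablation library.

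Among the gene lists 14 moved, 4 up and 10 down (camera; 0 with an estimated correlation, where 4 had an unadjusted p under 0.05, and 6 by fry). Cell-cell junction genes had a median of -0.93 (camera adjusted p = 1.56e-09, and adjusted p = 0.252 with an estimated correlation). Of 27 members 9 fell, among them the claudin gene Cldn4 by 2.82 ± 0.27, Dsg1a by 1.95 ± 0.21 and Nectin4 by 1.95 ± 0.22, and over the list alone 19 fell and 2 rose. Cholesterol synthesis genes had a median of -0.73 (camera adjusted p = 4.13e-08, and adjusted p = 0.381 with an estimated correlation), with 5 of 20 lower, 12 over the list alone. Dhcr7, the last step of the pathway, fell by 1.20 ± 0.15 and Fdft1 by 0.99 ± 0.14. In the activated keratinocyte list (median -0.86, camera adjusted p = 0.000117, and adjusted p = 0.284 with an estimated correlation) 6 of 17 fell, and 9 over the list alone. These were led by the small proline-rich envelope genes Sprr2d at -3.37 ± 0.53, Sprr1a at -2.76 ± 0.53 and Sprr1b at -2.24 ± 0.42. Upper hair follicle genes had a median of -1.11 (camera adjusted p = 0.0226, and adjusted p = 0.685 with an estimated correlation), and the call was lost without Lrig1 ablation 1 (camera adjusted p = 0.449). Past the threshold were Krt80 and Krt17, at -1.49 ± 0.32 and -0.78 ± 0.17, and the stem cell gene Lgr6, at 1.36 ± 0.27. Over the list alone 2 of 15 rose and 2 fell.

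The cell cycle list moved up, with positive values in 33 of 34 members and a median of 0.89 (camera adjusted p = 8.05e-12, and adjusted p = 0.49 with an estimated correlation), and 0 single members passed either over all genes or over the list alone (limma; 24 at an unadjusted p under 0.05). Basement membrane and matrix genes had a median of 0.54 (camera adjusted p = 0.000124, and adjusted p = 0.381 with an estimated correlation), and the call was lost without Lrig1 ablation 1 (camera adjusted p = 0.0547). In this list 3 of 27 rose, the laminin gene Lama5 by 1.05 ± 0.15, perlecan (Hspg2) by 0.96 ± 0.15 and periostin (Postn) by 0.79 ± 0.15, and over the list alone 6 rose and 1 fell. Basal keratinocyte genes had a median of 0.46 (camera adjusted p = 0.00504, and adjusted p = 0.689 with an estimated correlation) with 0 of 15 past either way and 5 at an unadjusted p under 0.05. The basal keratinocyte call was lost without Lrig1 ablation 1 (camera adjusted p = 0.74). Integrin and focal adhesion genes had a median of 0.19 (camera adjusted p = 0.0211, and adjusted p = 0.685 with an estimated correlation), and the call was lost without Lrig1 control 1 (camera adjusted p = 0.0603) or Lrig1 ablation 1 (0.324). In the latter list 1 of 26 passed, Itgb5, which fell by 1.05 ± 0.16, against the list's direction, with 1 up and 1 down over the list alone.

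Stress and interferon lists moved down. In the AP-1 list (median -0.44, camera adjusted p = 0.000256, and adjusted p = 0.381 with an estimated correlation) 1 of 23 fell, the small heat shock gene Hspb1, by 1.34 ± 0.18, and 5 fell over the list alone. The AP-1 call was lost without Lrig1 ablation 1 (camera adjusted p = 0.0812). Unfolded protein and integrated stress genes had a median of -0.39 (camera adjusted p = 0.0051, and adjusted p = 0.381 with an estimated correlation), with 3 of 18 lower and 6 over the list alone. The unfolded protein call was lost without Lrig1 ablation 2 (camera adjusted p = 0.552). Herpud1 was at -1.36 ± 0.20. Interferon response genes had a median of -1.88, or -1.67 with a member at 0 in both ablation libraries set to its bound (camera adjusted p = 0.00736, and adjusted p = 0.723 with an estimated correlation) with 0 of 26 past either way and 1 at an unadjusted p under 0.05. The interferon call was lost without Lrig1 ablation 1 (camera adjusted p = 0.252). Their median log2 value varied between libraries of a group, at 7.54 and 7.52 in K14 control, 4.13 and 9.06 in K14 ablation, 5.34 and 5.23 in Lrig1 control, and 2.93 and 3.78 in Lrig1 ablation.

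Beside the fall of differentiation genes stood a fall of endothelial and myeloid transcripts. Endothelial and mural genes had a median of -2.63 (camera adjusted p = 2.75e-05, and adjusted p = 0.129 with an estimated correlation). Of 9 members 4 fell, with Cdh5 at -4.44 ± 0.42, Emcn at -4.60 ± 0.58, Kdr at -3.78 ± 0.67 and Tie1 at -3.28 ± 0.57, and over the list alone 7 fell and 1 rose. Myeloid and Langerhans genes had a median of -1.97 (camera adjusted p = 2.75e-05, and adjusted p = 0.351 with an estimated correlation). Of 14 members 2 fell, the antigen presentation gene H2-Aa at -3.28 ± 0.61 and the lysozyme gene Lyz2 at -2.32 ± 0.46, against 10 over the list alone. In Lrig1 control these transcripts were above their K14 control level, as given further on.

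**Figure D2:**
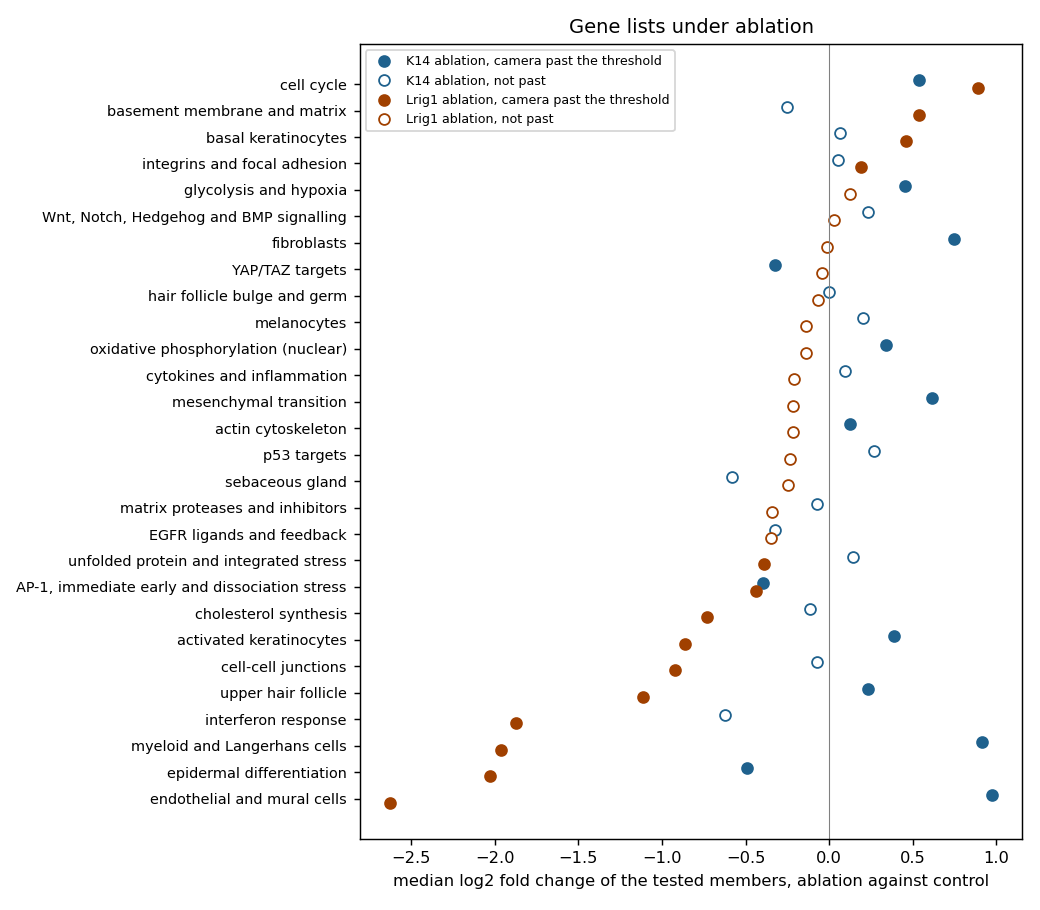
Median log2 fold change of the tested members of each of the 28 lists in K14 ablation and in Lrig1 ablation, each against its control; filled symbols passed the camera threshold. Epidermal differentiation lies at -0.49 in K14 and -2.03 in Lrig1, cell cycle at 0.54 and 0.89, and endothelial and mural cells at 0.98 and -2.63.

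The averaged effect, from 4 ablation against 4 control libraries, can pass through either population alone. Krt84 (ENSMUSG00000044294, chromosome 15, 101525026 to 101532820, minus strand) fell by 2.66 ± 0.17 (SE; limma adjusted p = 0.00087). Its means were 12520 ± 232 and 5341 ± 1070 in K14 control and ablation and 34410 ± 3560 and 2079 ± 546 in Lrig1 control and ablation (SD, n = 2 each). Krt2 (chromosome 15, 101810689 to 101818169, minus strand), a keratin of the upper epidermis, fell by 2.86 ± 0.31, Krt24 by 3.06 ± 0.27 and Krt36 by 2.89 ± 0.25. Wfdc17 fell by 4.21 ± 0.23, and Slc15a2, the fatty acid thioesterase gene Olah, the protease inhibitor gene Serpinb13, the proton pump gene Atp12a and Tprg fell as well, with values from -3.78 to -2.28. Pi15 rose by 3.74 ± 0.36 (limma adjusted p = 0.00331), Fscn1 by 2.28 ± 0.34, Slc38a4 by 2.10 ± 0.25, Vsnl1 by 1.77 ± 0.20 and Myadm by 1.72 ± 0.12. Kirrel, AI464131, Soga1 and Nup210 rose by 1.66 to 1.77.

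The differentiation list had a median of -1.27 (camera adjusted p = 9.16e-21, and adjusted p = 0.328 with an estimated correlation), with 14 of 25 lower and 23 over the list alone. Elovl4 fell by 1.55 ± 0.12 and Dsg1a by 1.43 ± 0.15. Cell cycle genes had a median of 0.72 (camera adjusted p = 2.9e-14, and adjusted p = 0.568 with an estimated correlation): Bub1b rose by 1.25 ± 0.23, the 1 of 34 past over all genes, and 25 rose adjusted over the list alone. Cholesterol synthesis (median -0.40, camera adjusted p = 1.56e-07, and adjusted p = 0.519 with an estimated correlation) had 2 of 20 lower, Dhcr7 and Fdft1, and 10 over the list alone. AP-1 genes (median -0.36, camera adjusted p = 1.66e-07, and adjusted p = 0.426 with an estimated correlation) had 3 of 23 lower, Atf3, the phosphatase gene Dusp1 and Hspb1, with values from -0.75 to -0.70, and 11 lower and 1 higher over the list alone. Junction genes (median -0.47, camera adjusted p = 6.71e-07, and adjusted p = 0.426 with an estimated correlation) had 5 of 27 lower, with Cldn4 at -2.03 ± 0.19, and 1 higher, the desmoglein gene Dsg2 at 0.64 ± 0.11, against 11 and 2 over the list alone.

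The other list calls of the average depended on single libraries. Matrix genes (median 0.10, camera adjusted p = 0.0287, and adjusted p = 0.687 with an estimated correlation) had 3 of 27 higher, Hspg2 by 1.07 ± 0.10, Lama5 by 0.70 ± 0.11 and tenascin (Tnc) by 1.26 ± 0.23, and 6 up and 1 down over the list alone. The list's p was 0.285 without K14 ablation 2 and 0.257 without Lrig1 ablation 1. Basal keratinocyte genes (median 0.23, camera adjusted p = 0.0253, and adjusted p = 0.747 with an estimated correlation) had 0 of 15 past, 2 over the list alone and 4 at an unadjusted p under 0.05. The basal keratinocyte call was lost without K14 ablation 1 (camera adjusted p = 0.0708), Lrig1 control 1 (0.0824) or Lrig1 ablation 1 (0.591). Interferon genes (median -1.21, camera adjusted p = 0.00846, and adjusted p = 0.747 with an estimated correlation) had 0 of 26 past either way (1 at an unadjusted p under 0.05). The interferon call was lost without K14 ablation 1 (camera adjusted p = 0.594) or Lrig1 ablation 1 (0.146). Fibroblast genes (median 0.27, camera adjusted p = 0.0287, and adjusted p = 0.436 with an estimated correlation) had 1 of 9 higher, Fbln1 by 1.21 ± 0.12, and 2 over the list alone. The p was 0.0518 without K14 ablation 1, 0.111 without Lrig1 control 1 and 0.154 without Lrig1 ablation 2. Endothelial genes (median -0.99, camera adjusted p = 0.0359, and adjusted p = 0.426 with an estimated correlation) had 1 of 9 lower, Cdh5 by 1.73 ± 0.30, and 2 over the list alone. These genes moved in opposite directions, with medians of 0.98 in K14 and -2.63 in Lrig1. The call was lost without any single ablation or Lrig1 control library.

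For the average 513 genes passed, 146 higher and 367 lower (limma; 3382 at an unadjusted p under 0.05; 449 by edgeR; 891 by DESeq2). The count was 53 and 54 without K14 control 1 and 2, 45 and 44 without Lrig1 control 1 and 2, 792 without K14 ablation 2, 1600 without Lrig1 ablation 1 and 2592 without Lrig1 ablation 2 (1253 higher and 1339 lower). Of 59 named genes past the threshold, 21 still passed without K14 control 1, K14 control 2 or Lrig1 control 1, 16 without Lrig1 control 2, 48 without K14 ablation 1 and 54 without K14 ablation 2, and 59 without either Lrig1 ablation library. Camera moved 10 lists, 4 up and 6 down (0 with an estimated correlation, where 2 had an unadjusted p under 0.05; 6 by fry).

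Some lists passed nowhere by camera. Fry called EGFR ligands and feedback down in Lrig1 ablation (adjusted p = 0.0407), the averaged effect (0.0354) and in Lrig1 control (0.0198). There 6 were up and 3 down (6 and 11 over the list alone). In the averaged effect the sebaceous gland list had a median of -0.44 (camera adjusted p = 0.0734), matrix proteases and inhibitors -0.23 (0.126), EGFR ligands and feedback -0.10 (0.193), Wnt, Notch, Hedgehog and BMP signalling 0.09 (0.456), p53 targets 0.11 (0.819) and melanocytes -0.26 (0.729). Over the 168 list results, the median, the mean and the direction of camera differed in sign in 16, of which 0 passed (camera).

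The overlap of the ablation calls asks whether the same genes moved in both populations. Of the genes higher with ablation, 9 were called in both (among them Fbln1, Hspg2, Megf6, Myadm, Pi15, Slc38a4, Soga1 and Vsnl1), against 0.138 for independent lists. Among those lower, 8 were called in both (Cobl, Cyp3a13, Dapl1, Errfi1, Grik4, Muc3a, Tprg and Wfdc17), against 0.527. The lists are not independent, because 1 fit gives both the same estimate of each gene's spread, and these expected numbers leave that out. With only the compared groups in the fit 0 calls were shared, as limma then called 0 in K14 (3565 at an unadjusted p under 0.05). Hspg2 and Muc3a, an intestinal-type mucin gene, are named as members of these small overlaps, and 2 genes including Krt17 were called in opposite directions. Across all tested genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.127 and a Spearman correlation of 0.0908. The number of shared calls was 0 without any of the 4 control libraries (limma), 7 without K14 ablation 1, 76 without K14 ablation 2, 169 without Lrig1 ablation 1 and 274 without Lrig1 ablation 2. The Pearson correlation was -0.00391 without Lrig1 ablation 1 and 0.233 without Lrig1 ablation 2.

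The difference of effects tests directly whether ablation acted otherwise in Lrig1 than in K14, and negative values mean a lower effect in Lrig1. Krt17 changed in opposite directions, higher in K14 and lower in Lrig1 ablation, for a difference of -2.48 ± 0.24 (SE; limma adjusted p = 0.0384). In all 4 ablation libraries it lay between 5722 and 7359, against 1901 and 2082 in K14 control and 12360 and 12650 in Lrig1 control. Vim, a filament of mesenchymal and migrating cells, differed by -4.44 ± 0.36 (limma adjusted p = 0.0272), at 38.6 and 54.2 in K14 control, 173 and 143 in K14 ablation, 611 and 816 in Lrig1 control and 95.8 and 125 in Lrig1 ablation. The named falls were Sele, whose size depends on the pseudocount because both Lrig1 ablation libraries are at 0, Slc15a2 (-5.57 ± 0.60), the envelope gene Sprr2b (-4.81 ± 0.62) and the red cell membrane gene Gypc (-4.50 ± 0.60). The antioxidant enzyme gene Gpx2, Krt84 and Elovl4 differed by -3.16, -2.83 and -1.96.

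Across the lists 13 differed, 2 upward and 11 downward (camera; 0 with an estimated correlation, where 5 had an unadjusted p under 0.05; 5 by fry). Differentiation genes differed by a median of -1.61 (camera adjusted p = 1.57e-17, and adjusted p = 0.157 with an estimated correlation), with Elovl4 among the 2 of 25 past and 20 past over the list alone. Activated keratinocyte genes differed by -1.82 (camera adjusted p = 3.02e-07, and adjusted p = 0.157 with an estimated correlation), with Krt17 the 1 of 17 past and 10 past over the list alone. Upper hair follicle genes differed by -1.50 (camera adjusted p = 0.000466, and adjusted p = 0.504 with an estimated correlation), with Krt17 again the 1 of 15 and 3 lower and 1 higher over the list alone. The upper follicle call was lost without Lrig1 ablation 1 (camera adjusted p = 0.217). Junction genes differed by -0.64 (camera adjusted p = 6.52e-07, and adjusted p = 0.26 with an estimated correlation), with 0 of 27 past, 8 over the list alone and 12 at an unadjusted p under 0.05. Actin genes differed by -0.38 (camera adjusted p = 0.00557, and adjusted p = 0.504 with an estimated correlation), with Cnn2 the 1 of 34 past and 2 over the list alone. Endothelial genes differed by -3.47 (camera adjusted p = 1.31e-06, and adjusted p = 0.157 with an estimated correlation), with Cdh5 and Emcn the 2 of 9 past and 6 over the list alone. Myeloid genes differed by -3.06 (camera adjusted p = 3.4e-08, and adjusted p = 0.201 with an estimated correlation), with 0 of 14 past, 11 over the list alone and 12 at an unadjusted p under 0.05.

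The remaining list calls depended on single libraries. Cholesterol synthesis differed by -0.50 (camera adjusted p = 0.000466, and adjusted p = 0.504 with an estimated correlation), with 0 of 20 past, 6 over the list alone and 8 at an unadjusted p under 0.05. The cholesterol call was lost without K14 ablation 2 (camera adjusted p = 0.0864). Oxidative phosphorylation differed by -0.42 (camera adjusted p = 0.00358, and adjusted p = 0.755 with an estimated correlation) and had 0 of 21 past either way, with 1 at an unadjusted p under 0.05. The oxidative phosphorylation call was lost without K14 ablation 2 (camera adjusted p = 0.0546) or Lrig1 ablation 2 (0.776). Glycolysis and hypoxia differed by -0.59 (camera adjusted p = 0.0239, and adjusted p = 0.755 with an estimated correlation) and had 0 of 23 past either way, with 5 at an unadjusted p under 0.05. The glycolysis call was lost without K14 ablation 1 (camera adjusted p = 0.243) or Lrig1 ablation 2 (0.997). Unfolded protein genes differed by -0.39 (camera adjusted p = 0.0173, and adjusted p = 0.504 with an estimated correlation), with 0 of 18 past, 3 over the list alone and 4 at an unadjusted p under 0.05, and the call was lost without Lrig1 ablation 2 (camera adjusted p = 0.495). Upward were matrix genes, by 0.48 (camera adjusted p = 0.00145, and adjusted p = 0.495 with an estimated correlation), and the call was lost without Lrig1 ablation 1 (camera adjusted p = 0.222). In this list 0 of 27 passed, with 2 up and 1 down over the list alone and 9 at an unadjusted p under 0.05, and Thbs1, a matrix glycoprotein gene, was at 2.13 ± 0.34 and fibronectin (Fn1) at -3.04 ± 0.72. Cell cycle genes were the other, by 0.29 (camera adjusted p = 0.019, and adjusted p = 0.795 with an estimated correlation), with 0 of 34 past either way and 0 at an unadjusted p under 0.05. The cell cycle call was lost without K14 ablation 2 (camera adjusted p = 0.418), Lrig1 control 1 (0.0613) or Lrig1 ablation 1 (0.177).

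In this test 36 genes passed, 2 higher and 34 lower (limma; 2718 at an unadjusted p under 0.05; 32 by edgeR; 293 by DESeq2). The count was 0 without either K14 control library or either Lrig1 control library (1370, 1496, 1568 and 1502 at an unadjusted p under 0.05 in limma). It was 83 without K14 ablation 1, 144 without K14 ablation 2 (54 higher and 90 lower), 2022 without Lrig1 ablation 1 (594 and 1428) and 551 without Lrig1 ablation 2 (133 and 418). Of 14 named genes past the threshold, 0 still passed without any of the 4 control libraries, 11 without K14 ablation 1 and 13 without K14 ablation 2.

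Lrig1 control against K14 control asks how the populations differed without ablation. Upper hair follicle genes were higher in Lrig1 in 13 of 15 members (13 up and 1 down over the list alone), with a median log2 difference of 2.73 (camera adjusted p = 6.11e-11, and adjusted p = 0.266 with an estimated correlation). Krt17 was higher by 2.65 ± 0.17 (SE; limma adjusted p = 0.00119) and Sostdc1, a BMP and Wnt antagonist, by 1.49 ± 0.14. Bulge and germ genes were higher in 10 of 15 (12 over the list alone), with a median of 1.57 (camera adjusted p = 3.95e-09, and adjusted p = 0.246 with an estimated correlation). The stem cell transcription factor gene Nfatc1 was higher by 2.0 ± 0.34 and Lhx2 by 1.83 ± 0.31. Differentiation genes were higher too, 15 of 25 (21 over the list alone), with a median of 1.33 (camera adjusted p = 9.69e-13, and adjusted p = 0.246 with an estimated correlation). The corneodesmosome gene Cdsn was higher by 5.0 ± 0.47 and the protease inhibitor gene Spink5 by 4.13 ± 0.45. The named rises were Rptn by 6.81 ± 0.97, Flg, which encodes filaggrin, by 5.89 ± 0.92, Sprr4 by 6.04 ± 0.97, Igfl3 by 6.15 ± 1.1 and Gsdma by 5.82 ± 1.1. Lower in Lrig1 were the collagenase gene Mmp13, at -3.16 ± 0.77, Slc4a8, at -2.86 ± 0.56, the carbonic anhydrase gene Car9, at -2.54 ± 0.47, the complement protease gene C1s1, at -2.34 ± 0.59, and the hyaluronan synthase gene Has2, at -2.31 ± 0.31.

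Junction genes were higher in Lrig1 control in 8 of 27 members (12 up and 1 down over the list alone), with a median of 0.53 (camera adjusted p = 0.000166, and adjusted p = 0.303 with an estimated correlation). So were 5 of 20 cholesterol synthesis genes (10 over the list alone), with a median of 0.48 (camera adjusted p = 0.000747, and adjusted p = 0.466 with an estimated correlation). The cell cycle and basal lists moved down by camera. The cell cycle list had a median of -0.79 (camera adjusted p = 3.95e-09, and adjusted p = 0.466 with an estimated correlation) with 0 of 34 past either way and 19 at an unadjusted p under 0.05. The basal list had a median of -0.98 (camera adjusted p = 0.00906, and adjusted p = 0.548 with an estimated correlation). In the basal list the 2 of 15 past went the other way, Krt15 by 0.82 ± 0.15 and Ptn by 0.85 ± 0.16, while 3 were higher and 8 lower over the list alone. Matrix genes had a median of -0.81 (camera adjusted p = 0.00101, and adjusted p = 0.344 with an estimated correlation). Of 27 members 8 were lower, such as Thbs1 at -2.21 ± 0.24 and Col7a1, the anchoring fibril collagen gene, at -1.62 ± 0.21, and 4 higher, such as Fn1 at 3.74 ± 0.51. Over the list alone 13 were lower and 5 higher. Integrin genes had a median of -0.31 (camera adjusted p = 0.00906, and adjusted p = 0.466 with an estimated correlation), with Itgb6 at -1.11 ± 0.23 among the 2 of 26 past, 1 lower and 1 higher, and 9 lower and 2 higher over the list alone.

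AP-1, cytokine, interferon and glycolysis lists moved down in Lrig1 control by camera. AP-1 genes had a median of -0.60 (camera adjusted p = 9.46e-06, and adjusted p = 0.289 with an estimated correlation), with 7 of 23 lower (13 lower and 2 higher over the list alone). Atf3 was at -1.49 ± 0.15 and Nr4a1 at -1.36 ± 0.20. Cytokine and inflammation genes had a median of -0.82 (camera adjusted p = 0.00339, and adjusted p = 0.421 with an estimated correlation), with 7 of 24 lower and 3 higher (11 and 3 over the list alone), among them the NF-kappaB feedback gene Tnfaip3 at -1.66 ± 0.22. Interferon genes had a median of -1.94 (camera adjusted p = 8.78e-05, and adjusted p = 0.504 with an estimated correlation), with 0 of 26 past either way and 3 at an unadjusted p under 0.05. Glycolysis and hypoxia genes had a median of -0.41 (camera adjusted p = 0.00112, and adjusted p = 0.466 with an estimated correlation), with Car9 the 1 of 23 past, over the list alone as well.

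Transcripts of other cell types were part of the same difference. Endothelial and mural genes were higher in Lrig1 control by a median of 4.03 (camera adjusted p = 5.63e-07, and adjusted p = 0.146 with an estimated correlation), 5 of 9 past and 7 over the list alone. Kdr, at 0 in both K14 control libraries, was at least 25-fold higher against a floor of 3 reads per library, and Cdh5 was higher by 4.53 ± 0.42. Myeloid and Langerhans genes were higher by 1.71 (camera adjusted p = 8.05e-05, and adjusted p = 0.289 with an estimated correlation), 6 of 14 past and 7 over the list alone. Examples were the epithelial and Langerhans adhesion gene Epcam at 2.45 ± 0.31, Ptprc at 3.68 ± 0.54 and Lyz2 at 3.07 ± 0.46. Fibroblast genes were higher by 1.21 (camera adjusted p = 0.00112, and adjusted p = 0.254 with an estimated correlation), 5 of 9 past and 5 higher and 1 lower over the list alone. Among them were the collagen genes Col3a1 at 2.44 ± 0.52 and Col1a1 at 1.95 ± 0.42. Summed over all members, T cell markers were 691 and 738 normalised reads in K14 control and 239 and 233 in Lrig1 control, mostly Thy1, with Cd3e at 7.11 and 15.8 against 4.66 and 1.41. Neutrophil markers summed to 26.4 and 12.8 against 68.7 and 59.2, with Il1b the most abundant, Merkel cell markers to 29.4 and 41.4 against 50.1 and 43.7, with Krt8 and Krt18, and erythroid markers to 17.3 and 30.5 against 25.6 and 31.0, mostly Alas2. Several of these genes were above the median tested gene in both K14 control libraries. These were 2 of the 12 fibroblast markers (Fbln1 and Ly6c1), 1 of the 11 endothelial and mural ones (Cspg4) and 3 of the 16 myeloid ones (Cd74, Itgam and Epcam), and also 1 of the 10 T cell ones (Thy1) and 3 of the 10 melanocyte ones (Pmel, Mitf and Gpnmb).

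**Figure D3:**
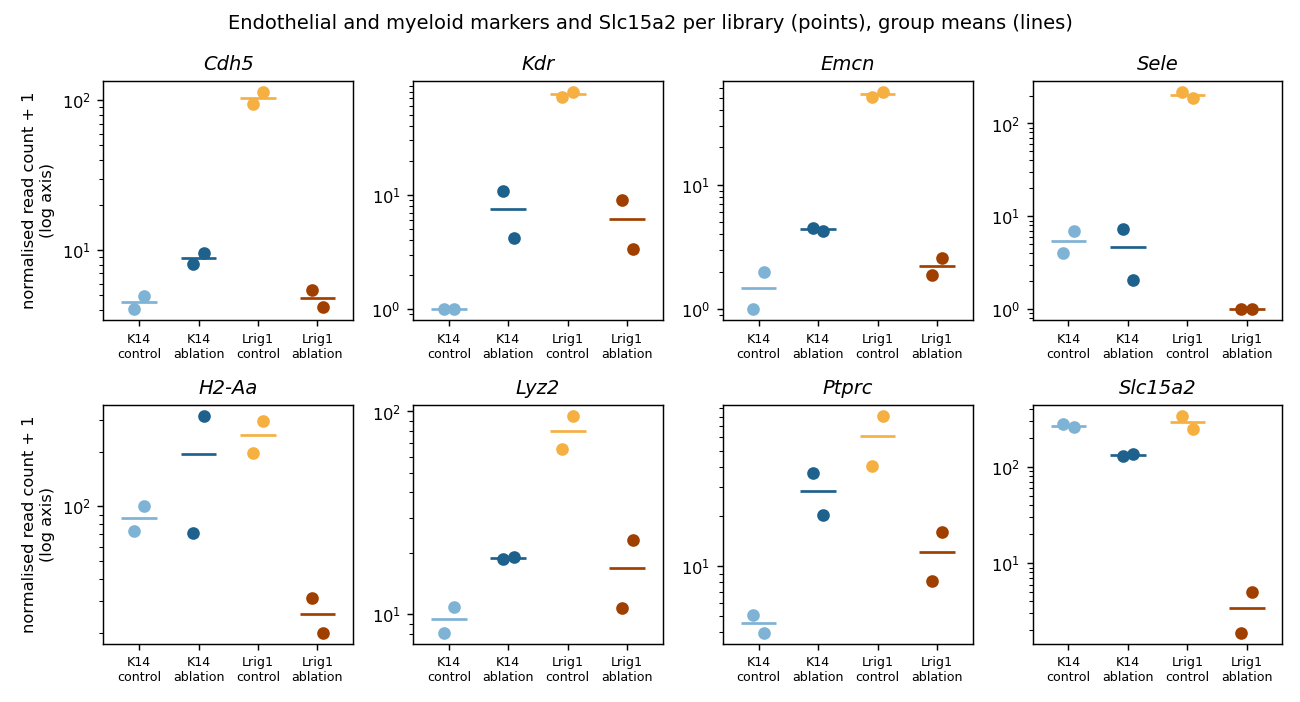
Normalised read count plus 1 (log axis) of Cdh5, Kdr, Emcn, Sele, H2-Aa, Lyz2, Ptprc and Slc15a2 in the 4 groups; each point is a library and each line a group mean. Cdh5 lies at 93.1 and 113 in Lrig1 control and at 3.05 to 8.58 in the other libraries.

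Between the controls 1594 genes passed, 1183 higher and 411 lower in Lrig1 (limma; 4423 at an unadjusted p under 0.05; 1393 by edgeR). The count was 91 and 96 without K14 control 1 and 2, 2 and 1 without Lrig1 control 1 and 2, and 3535 and 3539 without Lrig1 ablation 1 and 2, and limma fitted to the control libraries alone called 7269, 3815 higher and 3454 lower. With array weights it was 6747, 3529 higher and 3218 lower. Of 90 named genes past the threshold, 14 and 18 still passed without K14 control 1 and 2, 1 and 0 without Lrig1 control 1 and 2 (where 3 were not tested), and 89 without either K14 ablation library. Camera moved 16 lists, 8 up and 8 down (0 with an estimated correlation, where 5 had an unadjusted p under 0.05; 10 by fry), and leaving out a library ended none of these calls.

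Lrig1 ablation against K14 ablation asks how the populations differed once ablation had taken place. Bulge and germ genes were higher by a median of 1.70 (camera adjusted p = 1.33e-13, and adjusted p = 0.273 with an estimated correlation), 4 of 15 past and 14 over the list alone. Examples were Shisa2 at 2.32 ± 0.20, Postn at 1.63 ± 0.15, Lhx2 at 2.91 ± 0.31 and Tbx1 at 2.33 ± 0.33. Upper follicle genes were higher by 1.27 (camera adjusted p = 1.16e-08, and adjusted p = 0.302 with an estimated correlation), 2 of 15 past and 10 over the list alone. The 2 past were Sostdc1 at 1.22 ± 0.14 and the activin antagonist gene Fst at 1.27 ± 0.21. The named rises were the aggrecanase gene Adamts5 by 3.75 ± 0.58, the Wnt antagonist gene Nkd2 by 3.44 ± 0.43, Tenm3 by 3.33 ± 0.46, the IGF-binding protein protease gene Pappa by 3.32 ± 0.48 and Tshz2 by 3.13 ± 0.39. Lower in Lrig1 were Gypc, at -5.70 ± 0.42, Slc15a2, at -5.45 ± 0.42, the wound keratin gene Krt16, at -2.81 ± 0.43, Tnc, at -2.12 ± 0.33, and Nat8l, at -2.09 ± 0.31. Krt16 was at 7122 ± 1680 in K14 ablation and 1150 ± 802 in Lrig1 ablation (SD, n = 2 each; limma adjusted p = 0.0358).

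The activated keratinocyte list was lower by a median of -1.0 (camera adjusted p = 1.66e-05, and adjusted p = 0.273 with an estimated correlation), with Krt16 the 1 of 17 past and 7 over the list alone. Glycolysis and hypoxia genes were at -0.92 (camera adjusted p = 1.45e-10, and adjusted p = 0.302 with an estimated correlation), with 1 of 23 lower, Ndrg1, and 16 over the list alone. Oxidative phosphorylation genes were at -0.45 (camera adjusted p = 0.00025, and adjusted p = 0.615 with an estimated correlation), with 0 of 21 past either way and 2 at an unadjusted p under 0.05, and the call was lost without Lrig1 ablation 2 (camera adjusted p = 0.837). Interferon genes were at -2.91 (camera adjusted p = 5.29e-09, and adjusted p = 0.491 with an estimated correlation), 0 of 26 past either way with 16 at an unadjusted p under 0.05. Cytokine genes were at -0.98 (camera adjusted p = 7.5e-07, and adjusted p = 0.273 with an estimated correlation), with Tnfaip3 and Nfkbia the 2 of 24 past and 10 lower and 1 higher over the list alone. AP-1 genes were at -0.67 (camera adjusted p = 9.02e-08, and adjusted p = 0.273 with an estimated correlation), with Atf3 and Junb the 2 of 23 and 15 lower and 1 higher over the list alone. Unfolded protein genes were at -0.54 (camera adjusted p = 2.19e-05, and adjusted p = 0.273 with an estimated correlation), 0 of 18 past, 2 over the list alone and 10 at an unadjusted p under 0.05. Myeloid genes had a median of -0.73 (camera adjusted p = 0.00527, and adjusted p = 0.482 with an estimated correlation), with 0 of 14 past, 5 lower and 1 higher over the list alone and 7 at an unadjusted p under 0.05. The myeloid call was lost without Lrig1 ablation 1 (camera adjusted p = 0.23). Fibroblast genes were higher by 0.83 (camera adjusted p = 0.0227, and adjusted p = 0.302 with an estimated correlation), with 0 of 9 past, 2 higher and 1 lower over the list alone and 4 at an unadjusted p under 0.05. The fibroblast call was lost without K14 ablation 2 (camera adjusted p = 0.0604), Lrig1 ablation 1 (0.0618) or Lrig1 ablation 2 (0.167). Actin genes were at -0.30 (camera adjusted p = 0.011, and adjusted p = 0.491 with an estimated correlation), with 0 of 34 past either way and 12 at an unadjusted p under 0.05, and the call was lost without K14 ablation 1 (camera adjusted p = 0.0706) or Lrig1 ablation 2 (0.147). Cell cycle genes were at -0.52 (camera adjusted p = 3.66e-05, and adjusted p = 0.615 with an estimated correlation), with 0 of 34 past either way and 2 at an unadjusted p under 0.05. The cell cycle call was lost without K14 ablation 1 (camera adjusted p = 0.0883) or Lrig1 ablation 2 (0.445).

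Under ablation 121 genes passed, 84 higher and 37 lower in Lrig1 (limma; 2970 at an unadjusted p under 0.05; 134 by edgeR; 643 by DESeq2). Camera moved 13 lists, 3 up and 10 down (0 with an estimated correlation, where 5 had an unadjusted p under 0.05; 4 by fry). The gene count was 0 without either K14 control library or either Lrig1 control library (2118, 2122, 2200 and 2208 at an unadjusted p under 0.05 in limma). Without K14 ablation 1, Lrig1 ablation 1 or Lrig1 ablation 2 more calls were lower than higher. Limma fitted to the ablation libraries alone called 0, with 1293 at an unadjusted p under 0.05. The shared fit takes 1 spread per gene, although ablation pairs differed more than control pairs. Its p-values may thus be too small here and too large between controls. Of 26 named genes past the threshold, 0 still passed without any of the 4 control libraries, 21 without K14 ablation 1, 20 without K14 ablation 2 and 14 without Lrig1 ablation 2.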

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

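Of the tests in this part, those of a lower keratinocyte share, of swapped labels and of fewer differentiated cells, and the limit to balanced splits, were chosen only after the result was seen. The ablation effect differed between Lrig1 and K14 in 36 genes by a test of the difference itself (limma). The count was 0 without any of the 4 control libraries (1370, 1496, 1568 and 1502 genes at an unadjusted p under 0.05 in limma), and 83, 144, 2022 and 551 without K14 ablation 1, K14 ablation 2, Lrig1 ablation 1 and Lrig1 ablation 2. Among transcripts found in endothelial cells the differences of log2 fold changes were -6.23 for Emcn, -5.42 for Cdh5 and, as fitted, -7.24 for Sele, which depends on the pseudocount because both Lrig1 ablation libraries are at 0. Keratinocyte genes with a lower effect in Lrig1 were Sprr2b at -4.81, Krt84 at -2.83, Krt17 at -2.48 and Elovl4 at -1.96. Other genes were Slc15a2 at -5.57, Gypc at -4.50, Vim at -4.44, Gpx2 at -3.16 and Cnn2 at -1.76.

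Of the gene lists 13 differed between the ablation effects by camera, and 0 did with an estimated correlation (5 at an unadjusted p under 0.05; 5 by fry). Median differences were -3.47 for endothelial and mural genes, -3.06 for myeloid and Langerhans genes, -1.82 for activated keratinocytes, -1.61 for epidermal differentiation and -1.50 for the upper hair follicle. They were -0.64 for cell-cell junctions, -0.59 for glycolysis and hypoxia, -0.50 for cholesterol synthesis, -0.42 for oxidative phosphorylation, -0.39 for unfolded protein and integrated stress genes and -0.38 for the actin cytoskeleton. Upward were basement membrane and matrix genes, at 0.48, and the cell cycle, at 0.29. Single libraries ended some of these calls. Without K14 ablation 1 the camera adjusted p was 0.243 for glycolysis, and without K14 ablation 2 it was 0.0864 for cholesterol synthesis, 0.0546 for oxidative phosphorylation and 0.418 for the cell cycle. Without Lrig1 control 1 it was 0.0613 for the cell cycle. Without Lrig1 ablation 1 it was 0.217 for the upper follicle, 0.222 for matrix and 0.177 for the cell cycle, and without Lrig1 ablation 2 it was 0.776 for oxidative phosphorylation, 0.997 for glycolysis and 0.495 for unfolded protein genes.

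Endothelial and myeloid transcripts were high in the Lrig1 control libraries and lower in the Lrig1 ablation libraries. A lower share of keratinocytes there that raised all other cell types alike is argued against for the endothelial transcripts. Their mean log2 difference between the controls exceeded that of 5 melanocyte markers by 2.62 ± 0.83 (SE over markers), against 0.73 ± 0.65 for myeloid transcripts. Markers above the median tested gene in both K14 control libraries were left out. Summed fibroblast, melanocyte and T cell markers were lower (log2 ratios -0.108, -0.638 and -1.6) but 1.18, 0.52 and -0.40 without their top members Ly6c1, Gpnmb and Thy1. An even rise of myeloid transcripts thus cannot be excluded. A lower share with an uneven rise stays open for both. In second endothelial and myeloid sets 19 of 20 and 15 of 16 members were higher in both Lrig1 control libraries. Over the 14 and 9 tested members median log2 differences were 3.72 and 2.77 between the controls and -3.08 and -2.31 in Lrig1 ablation. Genes high in Lrig1 control alone pass the filter, favouring these medians. Endothelial and myeloid cells, or their RNA, may be the source, although the epithelial sort would remove such cells. The sets summed to 1626 and 1790 and to 220 and 345 normalised reads in Lrig1 control. A difference between the labelled populations stays open (untested).

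Lrig1 ablation 1 correlated better across genes with each K14 library (r = 0.9509 to 0.9635, the highest with K14 ablation 1) than with the other library of its own group (0.9442), which correlated with no library better than that. A swap of labels with a K14 library is argued against by the axis from the K14 control mean to the Lrig1 control mean, on which the K14 libraries lay between -0.00197 and 0.163 and Lrig1 ablation 1 and 2 at 0.332 and 0.553. Sex chromosome genes are argued against as the whole cause: without these 576 genes K14 ablation 1 still correlated better than Lrig1 ablation 2, by 0.0158. Sex effects on other genes stay open: Ddx3y was 0 in Lrig1 ablation 1, 0.708 in K14 ablation 1 and 1285 in Lrig1 ablation 2. So do a wrong label or outside swap of either Lrig1 ablation library, and an ablation effect toward both K14 groups (untested).

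Epidermal differentiation genes were lower in Lrig1 ablation (median log2 fold change -2.03). The authors' scaling is argued against by -1.8 under quantile normalization. Fewer differentiated cells and lower expression within cells cannot be told apart here. Members varied (SD 0.946, median SE 0.282), but members that basal cells also make would fall less with fewer differentiated cells. The list was higher in Lrig1 than in K14 control (median 1.33) and at -0.11 between ablation groups (camera adjusted p = 0.14). A difference in the Lrig1 control cells also stays open, untested.

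For the averaged ablation effect, with its 513 genes, the libraries were also split into other groups of 4 and 4 with the population in the model. Over all 34 splits, as first chosen, the highest of the others gave 2 genes, and K14 control 1 and 2, K14 ablation 1 and Lrig1 ablation 2 against the rest had 2798 at an unadjusted p under 0.05. Only 18 of them, the real one included, have 2 libraries of each population on each side, which is too few for a share under 0.05. The real split gave 178 genes in that model (limma; 2804 at an unadjusted p under 0.05) and the highest of the other balanced splits gave 0 (at most 1908 at an unadjusted p under 0.05), so 1 of the 18 gave as many.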

How the results depend on the processing

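In this part the Y-linked covariate and the omission of both second ablation libraries were chosen only after the result was seen. Counts of genes past the threshold are given in the order K14 ablation, Lrig1 ablation, averaged effect, difference of effects, control populations and ablation populations, where they were 34, 737, 513, 36, 1594 and 121, with 17 calls shared by both ablation effects. Each count stayed within 1.5 times of these with a pseudocount of 0.5, with median-ratio rescaling and with edgeR. An adjusted p of 0.1 gave 80, 1495, 1135, 261, 2567 and 337, with 32 shared. A log2 fold change of at least 1 left 272 for the average. The difference of effects gave 83 with a pseudocount of 5, 5 without the filter on low values, 13 with the stricter filter and 5 under quantile normalization. The ablation populations gave 75 without the filter. DESeq2 gave 203 for K14, 891 for the average, 293 for the difference and 643 for the ablation populations, with 74 shared. Without the variance trend limma gave 0 for K14 (2147 at an unadjusted p under 0.05; 32 by edgeR; 203 by DESeq2), 373 for Lrig1, 203 for the average and 6 for the ablation populations, with 0 shared. Array weights gave 477, 451, 812, 146, 6747 and 31, with 80 shared. With only the compared groups in the fit limma called 0 in K14 (3565 at an unadjusted p under 0.05), 170 in Lrig1, 7269 between controls and 0 between ablation groups (1293 at an unadjusted p under 0.05; 134 by edgeR; 643 by DESeq2), with 0 shared. The Y-linked covariate gave 105 for K14, 1222 for Lrig1, 383 for the difference, 2475 and 838 for the populations and 43 shared calls. Without both second ablation libraries the counts were 4147, 5797, 6131, 3963, 7336 and 2586, with 1700 shared; the spread then comes from the control libraries alone, which differed less within their pairs. For the other changes of count the cause was not tested.

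The replicate number as a block gave 21 calls for K14 and 1 for the difference, and moved no other gene count by over 1.5 times. Deviations of same-numbered libraries correlated at -0.0491 to 0.0838 across pairs of groups. Pairing stays open: Ddx3y was low in the ablation 1 libraries only.

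Leaving out each library in turn gave 0 to 740 genes for K14, 5 to 2498 for Lrig1, 44 to 2592 for the average, 0 to 2022 for the difference, 1 to 3539 between controls and 0 to 4041 between ablation groups (limma), with 0 to 274 shared. The libraries stand beside each comparison. The correlation of the ablation effects across genes went from -0.00391 to 0.233, the lowest without Lrig1 ablation 1 and the highest without Lrig1 ablation 2, against 0.127 with all libraries. It was 0.263 with the stricter filter, 0.00852 by DESeq2 and 0.251 without both second ablation libraries.

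Of the gene lists, camera with an estimated correlation called 0 in K14 ablation, 0 in Lrig1 ablation, 0 for the average, 0 for the difference and 0 between controls, where fry called 1, 6, 6, 5 and 10, and where 2, 4, 2, 5 and 5 had an unadjusted p under 0.05. The stricter filter ended 9 calls by camera, among them endothelial genes in K14 (adjusted p = 0.185) and the average (0.313), mesenchymal (0.107) and actin genes (0.0831) in K14 and the upper follicle in Lrig1 (0.114). The Y-linked covariate ended or turned 8, among them interferon in Lrig1 (0.562) and basal keratinocytes for the average (0.881), and leaving out both second ablation libraries 12. Of the other settings that keep every library and the same list test, each ended at most 2. Some lists turned direction by camera, whose sign can differ from that of the median. Without single libraries the median log2 fold change of interferon response, averaged ablation against control, ranged from -2.27 to -0.017 and turned without K14 ablation 1, and it was -0.077 with the Y-linked covariate. The upper hair follicle median in K14 ranged from -0.69 to 0.88 and turned without K14 ablation 2, and without both second ablation libraries it was -0.69 and past the threshold in the opposite direction (camera adjusted p = 0.0392). The cell cycle median ranged from -0.20 to 0.78 for the difference of effects, turning without Lrig1 ablation 1, and from -1.03 to 0.008 between ablation groups, turning without Lrig1 ablation 2. Without Lrig1 ablation 2 glycolysis turned in the difference of effects (range -1.16 to -0.014), as did oxidative phosphorylation between ablation groups (range -0.88 to 0.003). Without both second ablation libraries the oxidative phosphorylation median was 0.11 for the difference and 0.15 between ablation groups. The cause was not tested.

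Of 294 results of named genes, 24 stayed on the same side of the threshold under every setting (limma, edgeR and DESeq2). Of those past it 0 turned direction. Depth limits the low genes: a value under the 3-read floor of 2.12 to 4.23 could not be told from 0, so the log2 fold changes of Sele and of other genes near 0 depend on the pseudocount.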

Other observations

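In this part all tests and genes were chosen only after the result was seen. Krt18, a keratin of simple epithelia and of Merkel cells, was low in every control library and higher in the ablation libraries. It was at 5.08 and 6.89 normalised reads in K14 control, 43.9 and 41.8 in K14 ablation, 2.33 and 1.41 in Lrig1 control and 57.7 and 7.16 in Lrig1 ablation. The log2 fold change of Krt18, averaged ablation against control, was 2.81 ± 0.58 (SE; limma adjusted p = 0.0471), with adjusted p = 0.0493 by edgeR, 0.000208 by DESeq2 and between 3.66e-06 and 0.223 over the alternatives. The call was lost without K14 control 1 (0.223), K14 control 2 (0.192), K14 ablation 1 (0.0931), K14 ablation 2 (0.0761), Lrig1 control 1 (0.174) or Lrig1 control 2 (0.217). Its partner Krt8 was at 0.80 ± 0.35 (limma adjusted p = 0.274).

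Prox1, the transcription factor of lymphatic endothelium, was at 67.5 and 47.9 normalised reads in Lrig1 control and between 2.14 and 6.21 in the other libraries. The receptor gene Flt4 was at 123 and 135 against 2.03 to 19.5, and Mmrn1 at 368 and 426 against 6.09 to 32.8. Ramp2, which is made in endothelium, did not follow, at 368 and 330 in Lrig1 control and 326 and 285 in K14 control.

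The difference between the populations under ablation was compared with that between the controls, which shares no library with it. Across the 18140 tested genes, which are not independent replicates, the log2 differences had a Pearson correlation of 0.42, a Spearman correlation of 0.278 and a slope of 0.327. Of the 1594 genes called between controls, 1194 (74.9%) had the same sign between the ablation groups. In both comparisons 77 were called in the same direction, against 10.6 for independent lists, which these are not, since 1 fit gives both the same estimate of each gene's spread.

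The libraries differed in sex-linked transcripts, also within groups. Xist, made from the inactive X chromosome, was at 22490 and 23650 in K14 control, 25230 and 6948 in K14 ablation, 8679 and 12000 in Lrig1 control and 23380 and 66.1 in Lrig1 ablation. The Y-linked gene Ddx3y was at 519 and 390, 0.708 and 759, 851 and 703, and 0 and 1285 in the same order.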
